A study of Danio rerio with 12 samples.

How the data were processed

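Expression was measured on single-colour (Cy3) NimbleGen arrays in zebrafish embryos at 30 hours post fertilisation. There were 12 arrays in 4 groups of 3: iguana mutants, their wild type siblings, embryos kept in 100 µM cyclopamine from 4 to 30 hours post fertilisation, and embryos kept in 1% DMSO, the solvent, over the same hours. The labels call the samples of each group biological replicates, and groups and replicate numbers were taken from the sample titles. No array held values identical to those of another array, and correlations between arrays over all transcripts lay between 0.959 and 0.995.

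The deposited scanner files hold a raw intensity per probe, extracted with NimbleScan 2.4.31 per the file headers, with no background correction or normalization. Each array carries 385000 probes for 37157 transcripts, with 1 to 12 probes per transcript and 12 for 21894 of them, and 4307 control probes of random sequence. Mismatch values were 0 throughout. The authors' deposited value table holds a score per transcript and array: each column has a mean of 0, a median between 0.00582 and 0.0437 and a standard deviation between 0.983 and 1.01, so that it is read as a z score of the authors' RMA values, RMA being named in the submitters' processing notes. The log base and the centring behind that score are not given in the sources used here. Across transcripts the score correlated with the values computed here at r = 0.9997 on each of the 12 arrays. A further deposited file gives the authors' z ratio, also a score, for the mutant and for the cyclopamine comparison. Both z ratios correlated at r = 1 with the difference of the group means of the deposited z scores, mutant minus sibling and cyclopamine minus DMSO, which settles their direction. Another 12 columns there, with values per array, were not used.

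From the probe intensities, expression values were computed by RMA: a convolution model for the background on each array, quantile normalization over the 12 arrays, and median polish over the probes of a transcript with 10 iterations, on the log2 scale. Control probes were left out after the background step. R 4.3.3, limma 3.58.1, matrixStats 1.5.0 and version 1.17.8 of data.table were used. Group means were fitted on all 12 arrays with limma's lmFit and eBayes, so that the 4 groups shared an estimate of the spread, and p-values were adjusted by Benjamini-Hochberg over the 37157 transcripts, with a threshold of 0.05. The comparisons were mutant minus sibling, cyclopamine minus DMSO, and the difference of these log2 changes (the first minus the second). Error values given as SE come from this fit. A transcript counted as above background on an array when the median of its raw probe intensities exceeded the 95th percentile of the control probes there. Where no array of a group passed that level, a bound on the fold was computed, with each dim value set at the higher of its own and the lowest value among transcripts above background on that array. For the folds given here the bound equalled the estimate, so it carries the error of the estimate and is not a confidence limit.

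Gene symbols came from RefSeq accessions without versions, matched to a table for the assembly GRCz12tu. Of 3055 RefSeq transcripts on the array, 2663 matched, for 2650 genes, and the remaining 34494 transcripts have no symbol here. A gene with several transcripts was represented by the one with the highest mean over the 12 arrays. No transcript of dzip1, ptch1 or gli1 was among those matched, so these genes, dzip1 being the gene mutated in iguana, are not analysed here.

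Gene lists for tissues, pathways and stress responses were fixed before the data were examined, as were the designs, thresholds, alternative settings and the rule for naming genes. Of 32 lists, the 27 with at least 3 measured genes were tested against all other genes with a symbol by limma's camera, with its preset correlation of 0.01, adjusted over the lists. In all, 161 of 1041 list entries were measured, and some genes stand in more than 1 list. The naming rule took the 10 largest rises and the 10 largest falls past the threshold with groups that do not overlap, or, where no gene with a symbol passed, the 5 smallest p-values in each direction. It also took up to 4 members of each list described and always dzip1, ptch1 and gli1. Genes named outside this rule are said to be so, and some results under it are not reported here.

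Replicate numbers are shared between groups, so it was tested whether same-numbered arrays deviated together from their group means. For DMSO and cyclopamine, the correlations of these deviations over all transcripts were 0.678, 0.862 and 0.806, all above those of differently numbered arrays, so the numbers were taken to pair these arrays. A fit with the replicate number as a block within each experiment had been planned, and its values stand beside the cyclopamine results where they change a call. This fit also blocks sibling and mutant arrays, which the numbers do not pair and which enter its shared spread.

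The model was tested on simulated data with the real means and residual spread, in which 100 of 37157 transcripts had a log2 change of 1 and 100 a log2 change of 2. In the mutant comparison 35% and 84% of these were recovered with 12 false calls, and in the cyclopamine comparison 38% and 82% with 8 false calls. With the replicate block, the cyclopamine comparison recovered 67% and 95% with 7 false calls. With nothing changed, camera called 0 of the 27 lists in each comparison. The simulated noise was independent between transcripts and arrays, so this run could not show false list calls that arise from correlation among genes. Alternatives covered the background correction, normalization, probe summary, the deposited z scores, a filter that kept 27295 transcripts, the variance model, the threshold, the samples in the fit, the list test, the block, and each array left out. A slide or scan block was not run, because every array has its own image. The number of arrays limits the precision of every value.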

Results

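Whole-embryo expression was compared between iguana mutants and their wild type siblings, and between embryos treated with cyclopamine and with its solvent DMSO, all at 30 hours post fertilisation, with 3 biological replicates per group. The iguana gene dzip1 encodes a zinc finger protein needed for primary cilia and Hedgehog signalling, and cyclopamine is a plant alkaloid that blocks the Hedgehog signal transducer Smoothened. The study set the genes regulated through Dzip1 against those regulated through Hedgehog. Median raw probe intensity lay between 607 and 909 on the 12 arrays, and 65.9% to 77.3% of the 37157 transcripts lay above the control probes. That share was 70.9% ± 4.40 in mutants and 75.1% ± 1.98 in siblings (SD, n = 3 each, 2-sided exact permutation p = 0.2, the smallest possible being 0.1). The slope of probe signal from the 5' to the 3' end of transcripts, a measure that moves with RNA quality and labelling, was 0.0572 ± 0.00832 log2 per probe in mutants, 0.0593 ± 0.00253 in siblings, 0.0618 ± 0.0152 with cyclopamine and 0.0620 ± 0.0193 with DMSO (SD, n = 3).

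The first comparison asked which transcripts differ when Dzip1 is lost. In iguana mutants, genes of the sclerotome and Hedgehog target genes fell as lists. Of the 10 splits of the 6 arrays into 3 and 3, however, 3 gave at least these 2 lists, so chance is not excluded. The sclerotome and cartilage list shifted by a mean log2 change of -0.80 over its 3 measured genes (camera, adjusted p = 0.000119), although this call did not hold under a list test that estimates the correlation among genes (adjusted p = 0.155 with an estimated correlation). Its strongest members were pax1a, a transcription factor of the sclerotome, at -1.38 ± 0.22 (SE, 3 arrays per group; unadjusted p = 4.57e-05, limma adjusted p = 0.18), and twist2, a mesenchymal transcription factor, at -0.90 ± 0.22. On all 3 mutant arrays both lay below all 3 sibling arrays. Over all transcripts, 10.8% did not overlap between these groups, where chance gives 10%. The third member, matn3a, a cartilage matrix protein, was at -0.13 ± 0.38. Over all transcripts 0 of the 3 genes passed, and adjusted over the list alone 2 fell.

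The Hedgehog target list shifted by a mean of -0.79 over 3 genes (camera, adjusted p = 0.000663; adjusted p = 0.267 with an estimated correlation). It shares pax1a with the sclerotome list. The forkhead gene foxf2a was at -0.99 ± 0.32 (SE) and prdm1a, a regulator of slow muscle fate, at 0.00 ± 0.38. Again 0 genes passed over all transcripts and 2 fell adjusted over the list alone. The motor neuron list did not pass in mutants (mean -0.17, adjusted p = 0.463), although adjusted over the list alone 1 of its genes, phox2a, fell (-0.69 ± 0.20). Nor did slow muscle (mean -0.12, adjusted p = 0.436), cilia and basal bodies (mean -0.02, adjusted p = 0.895) or dorsal neural tube genes (mean -0.43, adjusted p = 0.0538) pass.

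Among single transcripts, limma found 1 past the threshold in mutants, and it fell. This was ZV700S00003893, which has no gene symbol here, with a log2 change of -3.41 ± 0.27 (SE) and an adjusted p of 0.0018. It was above the control probes on 3 of 3 sibling arrays and 1 of 3 mutant arrays. Of the genes with a symbol, 0 passed in limma, while 1206 transcripts had an unadjusted p under 0.05, fewer than the 1858 that chance gives. That count rests on a spread shared with the cyclopamine experiment, in which the pairing of arrays was not modelled. The fit of the 6 mutant and sibling arrays alone gave more than 1858, so the shortfall does not show that mutants hold less signal than chance. Among lower genes, pbx1b, a homeodomain factor (-0.70 ± 0.18), was with pax1a and twist2 among those with small unadjusted p-values, none past the threshold. Among higher genes the smallest belonged to rhbdd1 (0.80 ± 0.20), eif3hb (0.49 ± 0.14), abcg2d (0.71 ± 0.22), znf1015 (0.59 ± 0.18) and casp8l1. The last was above the control probes on 0 of 3 sibling arrays and 2 of 3 mutant arrays. Its change was 0.89 ± 0.27 (1.85-fold) and did not pass (adjusted p = 1.00). In the authors' deposited table, 170 transcripts had a z ratio above 1.96 in mutants and 452 had a z ratio as far below 0. Fits that left out cyclopamine replicate 2 or 3, which enter only through the shared spread, gave 3 and 2 mutant transcripts, and the fit of the 6 mutant and sibling arrays alone gave 3.

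The second comparison asked which transcripts respond to the Hedgehog inhibitor. With cyclopamine, motor neuron genes fell together. Their list shifted by a mean log2 change of -1.05 over 4 measured genes (camera, adjusted p = 6.79e-18; adjusted p = 0.00172 with an estimated correlation, 0.131 with that and the replicate block), and all 4 lay lower on every cyclopamine array than on every DMSO array. The homeobox gene mnx2a, expressed in motor neurons, was at -1.12 ± 0.16 (SE, 3 arrays per group; limma adjusted p = 0.0505). The related regulators of cranial motor and autonomic neurons phox2a and phox2bb were at -1.24 ± 0.20 and -1.32 ± 0.23, and chodl, a lectin of motor axons, was at -0.52 ± 0.16. Over all transcripts 0 of these genes passed, 3 with the block, and adjusted over the list alone 4 fell.

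Floor plate and ventral neural tube genes fell as a list, with a mean of -0.53 over 3 genes (camera, adjusted p = 0.000291; adjusted p = 0.0441 with an estimated correlation, 0.254 with that and the block). Of these, tal2, a factor of ventral neural cells, was at -0.88 ± 0.20 and foxj1a, a regulator of motile cilia, at -0.64 ± 0.22, while gata3 was at -0.05 ± 0.19. Adjusted over the list alone 2 of the 3 fell, and 0 over all transcripts. Slow muscle genes shifted by a mean of -0.35 over 9 genes (camera, adjusted p = 4.66e-05; adjusted p = 0.188 with an estimated correlation). The slow troponin gene tnni1c was at -0.96 ± 0.19, tnnc1b at -0.51 ± 0.19, tpm2 at -0.46 ± 0.18 and myl13 at -0.33 ± 0.21. Of the 9 slow muscle genes, 1 fell adjusted over the list alone, and 0 over all transcripts (5 and 1 with the block). The mean was -0.20 without cyclopamine replicate 3, and with 1 array left out myl13 ran from -0.50 to -0.18. Cilia and basal body genes shifted by a mean of -0.26 over 13 genes (camera, adjusted p = 0.000184; adjusted p = 0.226 with an estimated correlation). The axonemal dynein gene dnai1.2 was at -0.80 ± 0.19, the dynein assembly factor dnaaf2 at -0.57 ± 0.22 and bbs1, of the BBSome, at -0.40 ± 0.17. Of the 13, 1 fell adjusted over the list alone, and 0 over all transcripts (5 and 1 with the block), and the mean was -0.14 without DMSO replicate 2.

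Hedgehog target genes also shifted down with cyclopamine, by a mean of -0.60 over 3 genes (camera, adjusted p = 0.000678; adjusted p = 0.188 with an estimated correlation), with foxf2a at -0.95 ± 0.32, pax1a at -0.79 ± 0.22 and prdm1a at -0.07 ± 0.38. Of the 3, 2 fell adjusted over the list alone, and 0 over all transcripts (2 and 1 with the block). The mean was -0.35 without DMSO replicate 2, where foxf2a was at -0.63, and -0.91 without cyclopamine replicate 2. The sclerotome and cartilage list had a mean of -0.42 (camera, adjusted p = 0.00693; adjusted p = 0.188 with an estimated correlation), with twist2 at -0.34 ± 0.22 and matn3a at -0.12 ± 0.38. Adjusted over the list alone 1 of its 3 genes fell, and 0 over all transcripts. Its adjusted p was 0.0998 without cyclopamine replicate 3 and 0.0891 without DMSO replicate 3, where twist2 was at -0.23.

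Lists that rose with cyclopamine were Hedgehog pathway components and dorsal neural tube genes. The components list had a mean of 0.26 over 9 genes (camera, adjusted p = 0.000678; adjusted p = 0.416 with an estimated correlation), with the ligand gene ihha at 0.61 ± 0.16, scube2, needed for ligand release, at 0.56 ± 0.21, gli2b at 0.53 ± 0.45 and boc, a co-receptor, at 0.27 ± 0.21. In this list 1 gene rose adjusted over the list alone, and 0 over all transcripts (2 and 0 with the block). The ligand gene ihha was above the control probes on 1 of 3 DMSO arrays and 3 of 3 cyclopamine arrays. The dorsal neural tube list had a mean of 0.28 over 4 genes (camera, adjusted p = 0.0205; adjusted p = 0.424 with an estimated correlation), with pax7a at 0.43 ± 0.38, lmx1ba at 0.32 ± 0.17, gli3 at 0.21 ± 0.22 and wnt3a, above the control probes on 1 of 3 arrays in either group, at 0.17 ± 0.43. No member of it passed by either adjustment. With 1 array left out gli2b ran from 0.11 to 0.96, boc from 0.10 to 0.40, scube2 from 0.36 to 0.69, pax7a from 0.13 to 0.66, gli3 from 0.05 to 0.33 and wnt3a from -0.30 to 0.58. Without cyclopamine replicate 2 the means were 0.04 for the components (adjusted p = 0.194 in camera) and 0.03 for the dorsal list (0.466), and without DMSO replicate 3 they were 0.13 (0.0555) and 0.11 (0.305). They were 0.43 and 0.44 without DMSO replicate 2, and 0.42 and 0.48 without cyclopamine replicate 3, and the adjusted p for the dorsal list was 0.0512 without cyclopamine replicate 1.

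**Figure D1:**
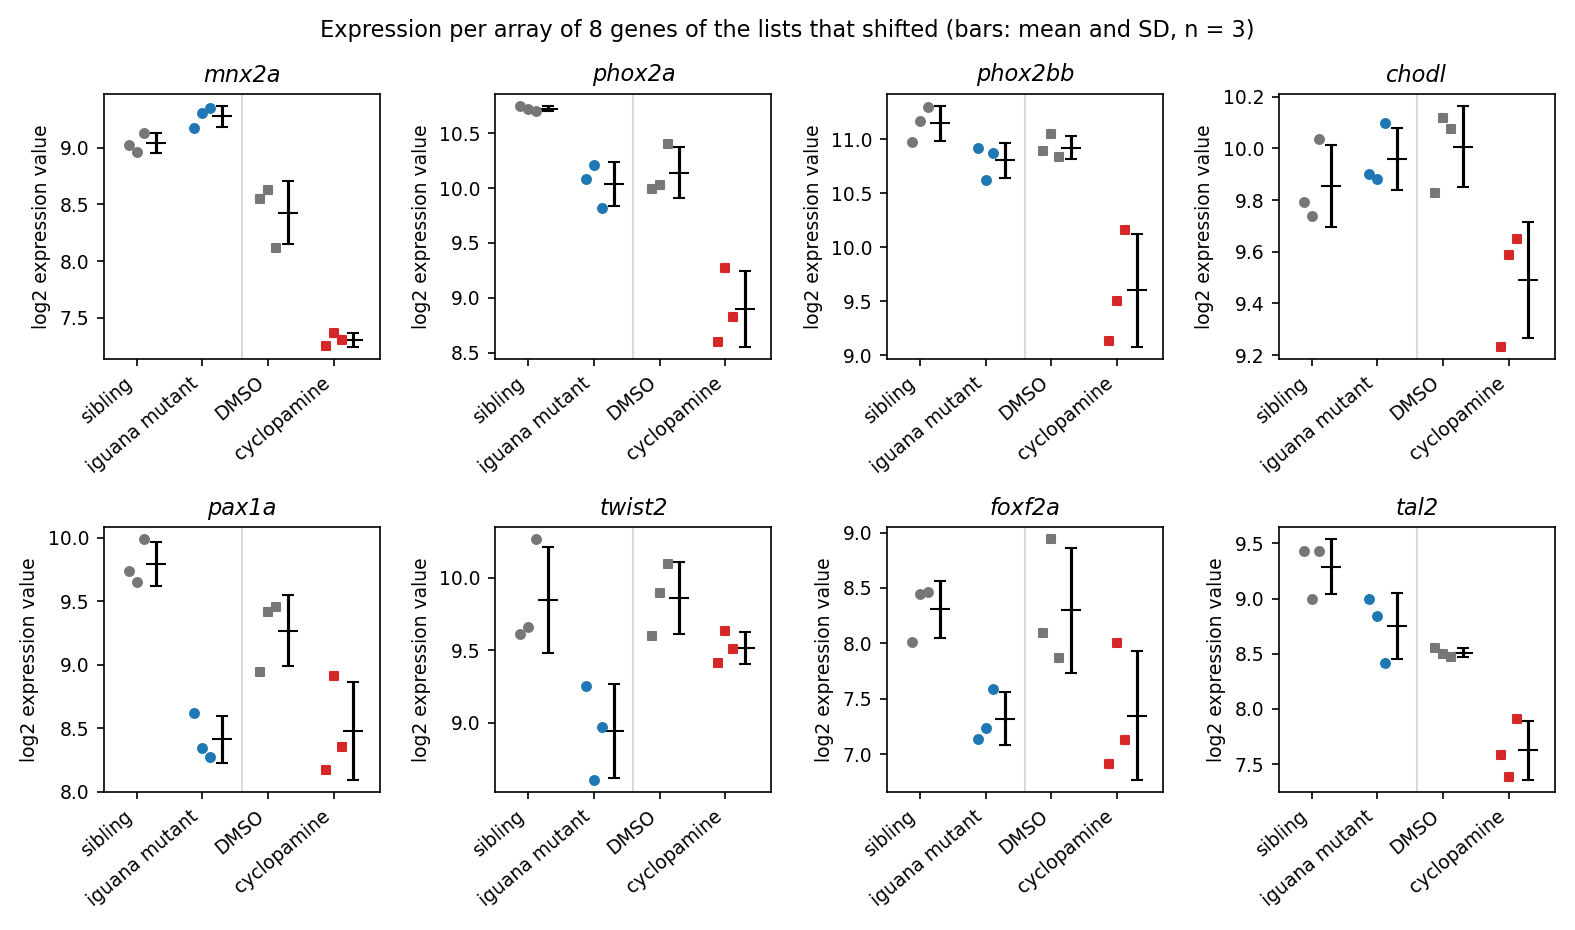
Log2 expression value (vertical axis) of 8 genes on each array in the 4 groups (horizontal axis), with points for single arrays and bars for the mean and SD of 3 arrays; the vertical axes differ and do not start at 0. The 4 motor neuron genes in the upper row lay lower on all 3 cyclopamine arrays than on all 3 DMSO arrays, and in the lower row pax1a and twist2 lay lower on all 3 mutant arrays than on all 3 sibling arrays. Over all transcripts, 4.91% did not overlap in the cyclopamine comparison and 10.8% in the mutant comparison, where chance gives 10% for unpaired arrays. The DMSO and cyclopamine arrays were taken as paired, so 10% is not the chance level for them.

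In limma, 9 transcripts passed the threshold with cyclopamine, all of them lower and none with a gene symbol. ZV700S00003893, the transcript that fell in mutants, was above the control probes on 3 of 3 DMSO arrays and 0 of 3 cyclopamine arrays. It was 25.4-fold lower (log2 change -4.67 ± 0.27, limma adjusted p = 5.77e-05), an estimate that dim signal may compress. ZV700S00005480 fell by 1.36 on the log2 scale (SE 0.15, adjusted p = 0.0166). In all, 810 transcripts had an unadjusted p under 0.05 where chance gives 1858, and 3092 had one with the replicate block. The block by replicate number was fitted in both experiments. Its numbers pair DMSO and cyclopamine arrays but not siblings and mutants, which also enter the shared spread. With this block 99 transcripts passed, 15 higher and 84 lower, including the 9. Of these, 12 have a gene symbol, and they are named after their values were seen. They include mnx2a, phox2a and phox2bb, the slow troponin tnni1c, foxf2a, the axonemal dynein gene dnai1.2, morn3, the growth factor binding protein gene fgfbp2b (-1.03 ± 0.18 without the block) and the cytochrome P450 gene cyp2aa9 (0.83 ± 0.25 without the block). The others were tectb, cd151 and c2cd4a, all lower. With the block in the DMSO and cyclopamine arrays only, chosen after seeing the data, 47 passed. Of the 12 genes, cyp2aa9, fgfbp2b, foxf2a, c2cd4a, tnni1c and dnai1.2 each passed in only 1 of 24 alternatives, the block in both experiments.

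Without the block the smallest unadjusted p-values among higher genes belonged to ihha, tfr2 (0.53 ± 0.16), a transferrin receptor gene, cyp2aa9, pth1b (0.67 ± 0.20), a parathyroid hormone gene, and ripply3 (0.57 ± 0.18), none past the threshold. Among lower genes they belonged to mnx2a, phox2a, phox2bb, fgfbp2b and morn3. In the authors' deposited table, 274 transcripts had a z ratio above 1.96 with cyclopamine and 265 had a z ratio as far below 0. Under the block the eye and lens list also fell (mean -0.16 over 10 genes, blocked adjusted p = 0.0412 against 0.062 without it) and the red blood cell list rose (mean 0.26 over 3 genes, 0.0412 against 0.191). Neither call held with an estimated correlation (adjusted p = 0.631 for both in camera, 0.375 and 0.316 with the block), and 0 of their members passed by either adjustment. The count of 9 became 2 without cyclopamine replicate 1, 2 without DMSO replicate 2, 3 without DMSO replicate 1, 4 without sibling replicate 1, 5 without sibling replicate 2 and 5 without mutant replicate 1. On the 6 cyclopamine and DMSO arrays alone limma called 0, with 486 at an unadjusted p under 0.05.

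The third comparison set both experiments against each other. Motor neuron genes were lower with cyclopamine than in mutants: the difference of their log2 changes, mutant minus cyclopamine, had a mean of 0.88 over 4 genes (camera, adjusted p = 2.4e-07; adjusted p = 0.035 with an estimated correlation, 0.535 with that and the block). It was 1.36 ± 0.22 (SE) for mnx2a, 0.98 ± 0.32 for phox2bb, 0.62 ± 0.23 for chodl and 0.55 ± 0.28 for phox2a. In mutants these genes were at 0.24 ± 0.16, -0.34 ± 0.23, 0.11 ± 0.16 and -0.69 ± 0.20. Adjusted over the list alone 3 of the 4 differed (4 with the block), and 0 over all transcripts. Cilia and basal body genes differed in the same direction (mean 0.24 over 13 genes, adjusted p = 0.048; adjusted p = 0.714 with an estimated correlation). Dorsal neural tube genes differed the other way (mean -0.72 over 4 genes, adjusted p = 0.00175; adjusted p = 0.705 with an estimated correlation), with pax7a at -0.81 ± 0.38 in mutants and wnt3a above the control probes on 0 of 3 mutant arrays, as did Hedgehog pathway components (mean -0.34 over 9 genes, adjusted p = 0.0186; adjusted p = 0.714 with an estimated correlation). In these 3 lists 0 genes passed over all transcripts or adjusted over the list alone. With the block, adjusted over the list alone, 3 dorsal genes, 2 components and 1 cilia gene differed. With the replicate block the vessel wall and red blood cell lists also differed (adjusted p = 0.0485 for both in camera), calls that did not hold with an estimated correlation (0.714 for both, and 0.643 and 0.535 with the block). The cilia mean was 0.12 without DMSO replicate 2, the components mean -0.12 and the dorsal mean -0.47 without cyclopamine replicate 2, and the components mean -0.21 without DMSO replicate 3. The adjusted p for the cilia list was 0.254 without cyclopamine replicate 3 or DMSO replicate 2, 0.0841 without mutant replicate 2, 0.0756 and 0.0654 without sibling replicates 2 and 1, and 0.0741 without DMSO replicate 1. For the components it was 0.149 without cyclopamine replicate 2, 0.127 without sibling replicate 3 and 0.0741 without DMSO replicate 1.

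**Figure D2:**
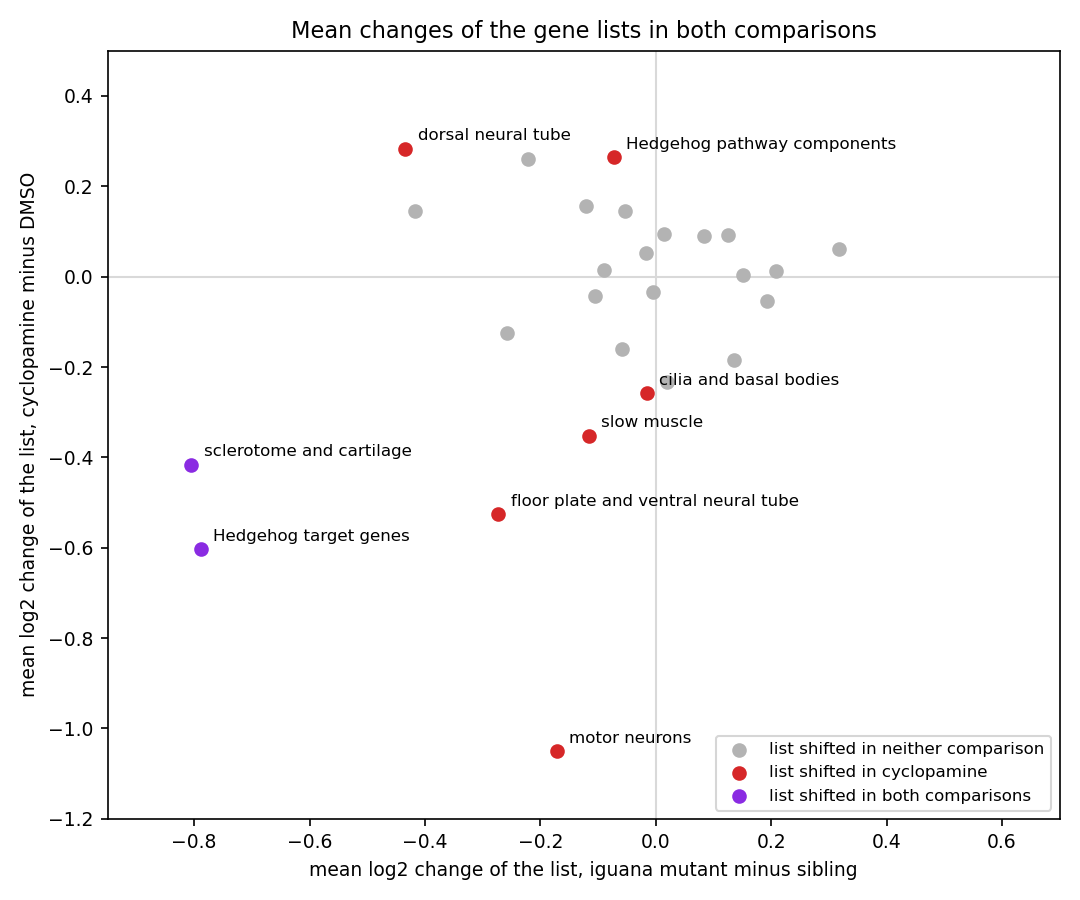
Mean log2 change of each of the 27 gene lists in mutants (horizontal axis, iguana mutant minus sibling) and with cyclopamine (vertical axis, cyclopamine minus DMSO), a point per list, coloured by the comparisons in which camera called the list. Motor neurons stand apart at -1.05 on the vertical and -0.17 on the horizontal axis, and the sclerotome and Hedgehog target lists lie lower in both.

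Among single transcripts, the change of ZV700S00005480 differed between the experiments: it fell with cyclopamine and was at 0.69 ± 0.15 in mutants (not past the threshold, adjusted p = 0.971), a difference of 2.05 ± 0.22 (limma, adjusted p = 0.0341). With the replicate block its adjusted p was 0.0893 and 0 transcripts passed in limma, with 4005 at an unadjusted p under 0.05. Of genes with a symbol 0 passed without the block, among 743 transcripts at an unadjusted p under 0.05. The smallest p-values with a larger value in mutants belonged to mnx2a, cd151 (0.95 ± 0.31), a tetraspanin gene, phox2bb, the tight junction gene cldn5b (0.56 ± 0.19) and morn3 (0.62 ± 0.21). Small p-values with a larger value under cyclopamine belonged to the protocadherin gene pcdh2g28 (-1.26 ± 0.40), cyp2aa9 (-1.08 ± 0.35), lmx1ba (-0.69 ± 0.23) and the splicing regulator gene mbnl1 (-0.68 ± 0.24). ZV700S00005480 passed in none of the 12 fits that leave out 1 array, its adjusted p reaching 0.246 without mutant replicate 1. In these fits limma called 1 other transcript without mutant replicate 3 and 0 without each of the other arrays, with 418 to 1636 at an unadjusted p under 0.05.

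The last comparison asked how far both experiments moved the same transcripts. ZV700S00003893 fell in both. Of the 9 transcripts that fell with cyclopamine, 8 were also lower in mutants, 7 of them at an unadjusted p under 0.05, with a median log2 change of -1.34 in mutants and -2.49 with cyclopamine over the 9. Of the 84 that fell with cyclopamine under the replicate block, 68 were lower in mutants, with medians of -0.34 and -1.11 over the 84. At an unadjusted p under 0.05 in each comparison, 55 transcripts were lower in both, 24 were higher in both and 17 went opposite ways. Independent lists would give 9.68, 4.02 and 12.6. Transcripts are not independent, so the excess alone does not exclude chance. In the authors' deposited table, 25 transcripts had a z ratio above 1.96 in both comparisons, 30 had one as far below 0 in both, and 2 were opposite. Across all 37157 transcripts, which are not independent replicates, the log2 changes correlated at r = 0.166 (Spearman rho 0.110). The r was -0.179 without cyclopamine replicate 3, 0.347 without DMSO replicate 3, 0.00773 without DMSO replicate 1 and 0.00352 with median scaling, and the shared count was 2 without cyclopamine replicate 2 or 3. With the replicate block in both experiments 15 transcripts passed the same way in both comparisons. The numbers do not pair siblings and mutants, though, and with the block in the DMSO and cyclopamine arrays only, fewer were shared.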

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

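The tests chosen only after the result was seen are the regroupings that part all pairs, those of transcripts at an unadjusted p under 0.05, the share of transcripts above the control probes set against the largest axis, the gradient covariate, and the block joined with an estimated correlation. Changes that differed between the mutant and the cyclopamine experiment, by a test of the difference itself, were those of ZV700S00005480 (2.05, mutant minus cyclopamine) and the mean shifts of the motor neuron list (0.88), the dorsal neural tube list (-0.72), the Hedgehog pathway components (-0.34) and the cilia and basal body list (0.24). With an estimated correlation the last 3 did not hold (adjusted p = 0.705, 0.714 and 0.714 in camera), and ZV700S00005480 passed neither with the block (limma, adjusted p = 0.0893) nor in any of the 12 fits that leave out 1 array. For single transcripts, 4 of 100 drawn regroupings of the 12 arrays within their experiments, of 200 possible, gave as many as the real 1, a share under 0.05, but the highest other value was 3797. Because the numbers pair DMSO and cyclopamine arrays, the 80 regroupings that part all 3 pairs were also run: 2 gave as many as the real 1 (highest other 10). For lists, 19 of 100 gave at least the real 4 (highest other 9), and 18 of the 80 that part the pairs did (highest other 11), so chance is not excluded for the number of lists that differ.

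The motor neuron difference was set against technical explanations. Its mean ran from 0.74 to 0.96 over the fits that leave out 1 of the 12 arrays, which argues against a single array. The highest adjusted p in these fits was 4.36e-05, from camera at its preset correlation. With the 5' to 3' signal gradient as a covariate the adjusted p was 1.47e-05 at the same preset correlation, which argues against that gradient as the whole cause. All 48 of 48 values of the 4 genes lay above the control probes, which argues against signal near background. Over 27 alternatives its adjusted p ran from 1.43e-08 to 0.535, the last with the replicate block and an estimated correlation together, the setting in which its call was lost. A candidate explanation is that motor neurons depend on Smoothened activity in a way that losing Dzip1 does not fully copy. The explanation comes from the same arrays, and no test of it was run. Cyclopamine was present from 4 to 30 hours, so the design cannot place such a dependence in time.

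The largest axis of variation held 36.6% of the variance and did not follow the groups. DMSO and cyclopamine replicates 2 lay at the low end and replicates 3 at the high end. It correlated with the signal gradient over 12 arrays (r = 0.856, rho 0.860), with r = 0.951 among DMSO and cyclopamine arrays, which are 3 pairs and not 6 independent arrays, so that no p is given, and 0.312 among mutant and sibling arrays. The difference of pairs 3 and 2 correlated at 0.626 between probes nearest the 5' and nearest the 3' end, between the bounds set for and against a cause along the transcript, and the axis had a rho of -0.608 with the share of transcripts above the control probes, so RNA quality and another difference shared by same-numbered samples cannot be told apart. No biological explanation of the axis was tested.

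The 6 arrays of an experiment have 10 splits into 3 and 3, too few for a share under 0.05. In the mutant experiment 1 of the 10 gave as many transcripts as the real 1 (highest other 0), and 3 of the 10 gave at least the real 2 lists (highest other 3). Chance is therefore not excluded for the mutant lists. In the cyclopamine experiment 1 of the 10 gave as many transcripts as the real 9 (highest other 0) and 1 gave as many lists as the real 8 (highest other 2). With the block, 1 of the 4 splits that part all 3 pairs gave as many as the real 99 transcripts (highest other 0), also too few. For the transcript that fell in both comparisons, 1 of 100 regroupings gave as many as the real 1 (highest other 0). The same held for 1 of the 80 that part the pairs (highest other 0). In the splits above no other grouping of either experiment called a transcript, so regroupings had little room to give a shared one. These shares therefore do not decide on chance. For the 79 transcripts at an unadjusted p under 0.05 the same way in both comparisons, 21 of 100 gave as many (highest other 1977). Among the 80 that part the pairs, 3 did (highest other 96). Both tests were chosen after the result was seen and their shares differ, so chance is not excluded. For the correlation of the log2 changes, 21 of 100 gave at least 0.166 (highest other 0.530), and 7 of the 80 did (highest other 0.315), so chance is not excluded. Only 2 of the 100 regroupings called more than 10 transcripts as different, and both point to a structure of the arrays: they set sibling 1, sibling 2 and mutant 2 against mutant 1, sibling 3 and mutant 3, and the third DMSO and cyclopamine pair with an array of the first pair against the second pair with the other.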

How the results depend on the processing

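Tests chosen only after the result was seen are the block in the DMSO and cyclopamine arrays only, the gradient covariate, the adjustment over transcripts with a symbol alone, and the replicate block joined with an estimated correlation. The transcript counts were 1 in mutants, 9 with cyclopamine, 1 for the difference and 1 shared, and the list counts 2, 8 and 4. The causes of the changes given here were not tested.

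The mutant count was 4 with a saddle-point background and 5 with no background correction, with 2 and 3 shared transcripts. The count for the difference was 0 in limma with median scaling (1127 at an unadjusted p under 0.05), the mean of the probes (767), an intensity trend with a robust prior (690) and a threshold of 0.01 (743), which also took the cyclopamine count to 2. Median scaling took r to 0.00352, and both it and leaving out dim transcripts took the lists that differ to 2. Median scaling, which does not bring the distributions together, left a median over all transcripts of 0.18 in mutants and -0.09 with cyclopamine. Quantile normalization left 0.03 and -0.01. Fitting 6 arrays alone gave 3 mutant and 0 cyclopamine transcripts in limma, with 2314 and 486 at an unadjusted p under 0.05. Requiring an adjusted p in only 1 comparison gave 7 shared transcripts.

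With the replicate block, which pairs same-numbered arrays, the counts were 70, 99 and 0 (5764, 3092 and 4005 at an unadjusted p under 0.05 in limma), with 15 shared. The numbers do not pair siblings and mutants: the correlations of their deviations were 0.0665, 0.155 and 0.453, and sibling 1 went with mutant 2 at 0.501. With the block in the DMSO and cyclopamine arrays only, 16 and 47 passed, with 4 shared, and with the gradient as covariate 12 and 28, also with 4. Adjusted over transcripts with a symbol alone, limma called 0, 1 and 0, the 1 being mnx2a, with 109, 58 and 65 at an unadjusted p under 0.05. A slide or scan block was not run.

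Camera with an estimated correlation and fry each called 0, 2 and 1 lists; the calls that held were motor neurons and floor plate with cyclopamine and motor neurons for the difference. With the replicate block and an estimated correlation together camera called 0, 0 and 0. Over all settings the called lists passed 315 times, and the other 63 times they kept their direction and did not pass. For single genes 1556 results were unchanged, 33 gained and 70 lost a call, the losses all in unnamed transcripts, and 17 changed sign, none of them called. These were prdm1a with cyclopamine (0.00531 with the saddle-point background, 0.0189 with none, 0.0644 with the mean of the probes) and in mutants (-0.00839 with quantile normalization within experiments, -0.0285 with the mean of the probes, -0.0777 with the gradient), and otherwise fits without 1 array.

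Without 1 array, the counts ran from 1 to 3 in mutants, 2 to 10 with cyclopamine, 0 to 1 for the difference and 1 to 2 shared, and the lists from 2 to 3, 5 to 12 and 2 to 6. The r ran from -0.179 without cyclopamine replicate 3 to 0.347 without DMSO replicate 3. The log2 changes of genes that changed sign ran from -0.18 to 0.17 for prdm1a in mutants, -0.43 to 0.31 for prdm1a, -0.25 to 0.16 for gata3, -0.34 to 0.21 for matn3a and -0.30 to 0.58 for wnt3a with cyclopamine, and -0.33 to 0.24 for matn3a in mutants. Signal near the control probes compresses folds, so changes from or to that level may be understated.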

Other observations

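Tests chosen only after the result was seen are those of chance placement near dzip1 and of the same region with cyclopamine. The protocadherin genes were also counted only after their values were seen, and they were not tested as a group. Other lists fixed in advance passed camera in neither comparison without the block. For endothelium the mean was -0.11 in mutants (adjusted p = 0.907) and -0.04 with cyclopamine (0.720). For vessel wall and mural cells it was -0.12 (0.511) and 0.16 (0.119), and for red blood cells -0.22 (0.502) and 0.26 (0.191). Cholesterol synthesis, a sterol pathway, stood at 0.08 (0.463) and 0.09 (0.201), fast muscle at 0.14 (0.770) and -0.18 (0.201), notochord at -0.05 (0.907) and 0.14 (0.465), and differentiated neurons at -0.26 (0.463) and -0.12 (0.201).

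Stress lists did not pass either. The p53 list had a mean of 0.21 in mutants (camera, adjusted p = 0.463) and 0.01 with cyclopamine (0.923). Its member sesn2, named outside the rule, was at 0.66 in mutants, past the threshold adjusted over the list alone (limma, adjusted p = 0.0415). Heat shock genes were at 0.15 (0.457) and 0.00 (0.867), xenobiotic and oxidative stress genes at 0.01 (0.922) and 0.09 (0.488), and the cell cycle at -0.01 (0.922) and -0.03 (0.822).

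Among 28 protocadherin genes, all with symbols that begin with pcdh1 or pcdh2, 26 were lower in mutants, with a median of -0.57. With cyclopamine 12 were lower, with a median of 0.03. In mutants 9 were lower at an unadjusted p under 0.05 in limma and 0 higher at that level. These 9 were all pcdh2 genes, while the pcdh1 genes lay between -0.16 and 0.03. Under other background, scaling and summary choices 25 or 26 were lower, with a median of -0.26 with no background correction and -0.37 with the saddle-point background. None passed over all transcripts in limma, and whether these paralogs share probes was not examined.

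Genes with low unadjusted p-values in mutants gathered near dzip1 in the gene order of GRCz12tu. Of the 50 measured genes nearest to it, 9 had an unadjusted p under 0.05 in limma. Among them were pbx1b (-0.70), casp8l1 (0.89) and, named outside the rule, scn1lab (-1.01), bmpr2a (-0.68) and hmox1b (0.85). Of 1413 overlapping windows of 50 genes, 1.06% held as many, which argues against chance placement, while with cyclopamine 70.28% of windows held at least the 1 seen there, which argues against a property of the region apart from the mutation. A median of 91.7% of the probes moved with their gene, but these genes were picked by p on a median summary of the same probes, so this decides nothing and variants under the probes stay open. Sequence linked to the mutation, carried by mutants and less by siblings, is a candidate explanation of either kind, in expression or in probe binding, so that some of these changes may not follow from the loss of Dzip1.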
